A study of Homo sapiens with 60 samples.

How the data were processed

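HT29 cells were exposed to extract or vehicle for 24 h, per the labels' protocols. The vehicle was 0.1% DMSO per the sample labels and 2% DMSO per the series description, and this difference could not be settled. No DMSO percentage was found for the extract libraries. Strand-specific libraries of mRNA were sequenced with paired 100 bp reads, per the labels' protocols. The submitters' processing notes name FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.3a and RSEM 1.3.3 with the genome build GRCh38, and do not state the annotation release or whether the counting used strand. The authors deposited 1 table of expected counts per gene and library, not normalized, with 60675 Ensembl gene IDs and 60 libraries. Per the values, 89.9% lay within 1e-09 of a whole number, and the others carry the fractions with which reads that match several genes are split. The series description also names wortmannin as a positive control, for which the table holds no library. Symbols were found for 57055 of the IDs, and gene positions were taken from GENCODE release 29 on GRCh38.

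Groups, comparisons, gene lists, the rule for the genes named and the alternatives were fixed before the data were examined. Expected counts were rounded to whole numbers. Genes were kept by filterByExpr of edgeR 4.0.16 (16890 genes), libraries were scaled by TMM, and 1 quasi-likelihood model was fitted to the 54 libraries of the 19 groups with 2 or 3 libraries, with the group as the only term, in R 4.3.3. The biological coefficient of variation was 9.71%. Each of the 18 extract doses was compared with the vehicle, each high with its low dose, and the extracts of 1 library set at the high dose, which makes 27 comparisons. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and errors after ± are standard errors for log2 fold changes and SD between libraries for CPM. These p-values measure only the spread between the libraries of this series. With 3 libraries per group the tests rest on a spread shared over all groups.

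Gene lists (32 lists, 777 of 780 entries found in the table) covered targets of the aryl hydrocarbon receptor, of PXR and CAR, NRF2, ATF4, LXR, p53 and NF-kB, stress responses, lipid, glucose and mitochondrial metabolism, the cell cycle, interferon, immediate early, Wnt and intestinal lineage genes, metallothioneins, autophagy, ribosomal genes, histones, and markers of fibroblasts, leukocytes, hepatocytes and endothelium. The 30 lists with at least 5 tested genes were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Where the report gives 1 p for a list called with all 54 libraries, the call held with an estimated correlation. The other settings used the preset correlation only. Members of a list that rose or fell were counted over all genes tested and adjusted over the list alone.

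Genes named in the text were drawn, for each high dose, from the 6 largest rises and falls among called genes with a mean of at least 5 CPM in 1 group and every treated library outside the range of the vehicle libraries, and up to 4 called genes of each called list and of the lists for the aryl hydrocarbon receptor, NRF2, ATF4, cholesterol synthesis and G2/M. Genes drawn from lists did not have to reach 5 CPM or lie outside the range of the vehicle libraries. For high against low doses 3 each way were drawn and between extracts 4. Clone names, antisense and noncoding symbols were passed over, and some genes drawn by this rule are not named in the text. For Polygalae Radix and Aucklandiae Radix, with 1 library per dose, log2 ratios of CPM to the vehicle mean are given without a test, for genes drawn from the 6 largest ratios each way with the same direction at the medium dose, and the median of a list is set against 10000 random lists of the same size matched on expression.

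The steps were tested on simulated data with 200 changed genes among 16890. The simulated data held no library unlike the others of its group. For Yijin-tang high dose against vehicle, 74.2% of genes changed 1.5-fold, 94.0% changed 2-fold and 100% changed 4-fold were recovered, and 2.72% of calls were false. For Soshiho-tang high dose against vehicle, with 2 treated libraries, 72.7% of genes changed 1.5-fold, 92.5% changed 2-fold and 98.5% changed 4-fold were recovered, and 6.88% of calls were false, which is above the nominal 5%. The alternatives were DESeq2 1.42.0, RLE normalization, no filter on low counts, only the compared groups in the fit, the replicate number as a block, another prior count, and each library left out in turn. A fit without the library labelled Yijin-tang low dose replicate 2 and the library labelled Soshiho-tang high dose replicate 3 was chosen after seeing the data. The labels do not say that replicate numbers mark a shared batch. In 1 of 27 comparisons, Schisandrae Fructus medium dose against vehicle, the deviations of all 3 same-numbered pairs correlated above 0.1 (0.199 to 0.462), so that the numbers were taken to pair the libraries there. This rule needed 3 pairs, so the comparisons with Soshiho-tang, which had fewer, could not meet it.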

Results

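Messenger RNA levels were measured by RNA sequencing in HT29, a human colorectal adenocarcinoma cell line, after 24 h with herbal extracts or with the vehicle, DMSO. The 60 libraries fell into 25 groups, which were the vehicle (n = 3) and 8 extracts at 3 doses each. Yijin-tang and Soshiho-tang, decoctions of several herbs, were water extracts, and Liriopis seu Ophiopogonis Tuber, Schisandrae Fructus, Longan Arillus, Zizyphi Semen, Polygalae Radix and Aucklandiae Radix, each 1 herb, were ethanol extracts. The high, medium and low doses were 500, 100 and 20 µg/mL, except for Polygalae Radix (380, 76 and 15.2 µg/mL) and Aucklandiae Radix (370, 74 and 14.8 µg/mL). Each dose had 3 libraries, except for Soshiho-tang with 2 and for Polygalae Radix and Aucklandiae Radix with 1. Library totals ran from 18161717 to 35128954 expected counts. Read from the first part of the library names, the vehicle libraries form library set C1 and the extract libraries sets 8 to 11. The labels do not say what these parts mark, and the titles give BatchC for all 60 libraries. In a comparison with the vehicle the extract and the library set cannot be told apart. Nor can a difference in DMSO, whose percentage was found for the vehicle only. Comparisons of the high with the low dose of 1 extract, and of both extracts of 1 set, lie within a set.

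Of the 54 libraries in groups with replicates, 2 stood apart from the others in their transcripts. In the library labelled Yijin-tang low dose replicate 2, genes of cytosolic ribosomal proteins held 10.7% of the counts, against at most 5.53% in any other library, and 30 genes lay at least 4-fold above and 140 at least 4-fold below the other 2 libraries of its group. Its deviations from those libraries had an SD of 0.87 log2 units, against at most 0.18 in the 45 libraries of other groups of 3. The library labelled Soshiho-tang high dose replicate 3 held transcripts that were near 0 elsewhere, chosen for mention after their values were seen: hemoglobin genes HBB at 3.36 and HBA1 at 3.33 CPM (counts scaled by library size), and the leukocyte genes HLA-DRA at 3.93, S100A9 at 3.26 and LAPTM5 at 4.69 CPM. The highest level of these 5 genes in the other libraries was 0.566 CPM, for LAPTM5.

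Yijin-tang at the high dose (n = 3 against 3) raised transcripts of chemokines and other NF-kB targets. CXCL1, a chemokine that attracts neutrophils (ENSG00000163739, chromosome 4, 73869393 to 73871242 on GRCh38), rose by 3.20 ± 0.21 (adjusted p = 4.01e-14) on the log2 scale, to 19.0 ± 2.51 CPM against 2.06 ± 0.494. CXCL8, another neutrophil chemokine, rose by 1.30 ± 0.13, PI3, which encodes the elastase inhibitor elafin (ENSG00000124102, chromosome 20, 45174876 to 45176544), by 2.10 ± 0.18, the apoptosis inhibitor BIRC3 by 0.94 ± 0.13 and the adhesion molecule ICAM1 by 0.77 ± 0.15. Of the genes for NF-kB and chemokines, 9 of 20 rose (12 adjusted over the list alone, camera adjusted p = 6.26e-29). CCL20 was at 2.10 against 0.0937 CPM. Of aryl hydrocarbon receptor targets, 5 of 11 rose (6 adjusted over the list alone, camera adjusted p = 9.11e-17). They were led by the cytochrome P450 genes CYP1A1 at 2.67 ± 0.17 and CYP1B1 at 0.86 ± 0.06 and by the retinaldehyde dehydrogenase ALDH1A3 at 0.67 ± 0.07. In the vehicle CYP1A1 averaged under 5 CPM. Of NRF2 targets, 6 of 28 rose (16 adjusted over the list alone, camera adjusted p = 1.47e-16). Risers were the cystine transporter SLC7A11 at 0.70 ± 0.10 and both subunits of the enzyme that starts glutathione synthesis, GCLM at 0.55 ± 0.08 and GCLC at 0.46 ± 0.05. The largest falls were those of ANXA13, an annexin of intestinal epithelium (ENSG00000104537, chromosome 8, 123680794 to 123737407), at -0.66 ± 0.08 (adjusted p = 1.36e-07), FAM131B at -0.62 ± 0.14, MYCL at -0.60 ± 0.09, SOX4 at -0.54 ± 0.13, OSR1 at -0.54 ± 0.10 and RGS2 at -0.53 ± 0.11. Of immediate early and MAPK feedback genes, 4 of 28 fell (10 adjusted over the list alone, camera adjusted p = 6.44e-10). Among them were the growth factor response genes EGR1 at -0.51 ± 0.13, FOS at -0.46 ± 0.11 and MYC at -0.36 ± 0.08. This list was called lower in 16 of the 18 comparisons with the vehicle at the preset correlation, and in 3 with an estimated correlation. Goblet and secretory cell genes had a median of -0.26, and 1 of 17 fell (4 adjusted over the list alone, camera adjusted p = 7.53e-06), which was BCAS1 at -0.39 ± 0.05. Of interferon response genes 1 of 36 rose (11 adjusted over the list alone, camera adjusted p = 4.04e-09), namely IFIT5 at 0.38 ± 0.09.

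By edgeR's quasi-likelihood test, 177 of 16890 genes passed (94 higher, 83 lower) in Yijin-tang high dose against vehicle, 20 of them at least 2-fold higher and 3 at least 2-fold lower. The count moved to 104 and 80 without vehicle replicate 1 or 3 and 88, 86 and 90 without high dose replicate 1, 2 or 3. In the fit without the 2 libraries that stand apart 1239 genes passed, 177 of these 177 among them. With single libraries left out, the highest adjusted p was 0.112 for FAM131B, 0.126 for SOX4, 0.0779 for RGS2, 0.271 for EGR1, 0.121 for FOS and 0.126 for MYC.

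At the lower doses of Yijin-tang some of the genes for NF-kB and chemokines were above the vehicle. CXCL1 rose by 2.69 ± 0.21 at the medium and 1.97 ± 0.22 at the low dose, and CYP1A1 by 1.06 ± 0.21 at the medium dose (adjusted p = 0.0273), with 0.47 ± 0.23 at the low dose (adjusted p = 0.266). Of the genes for NF-kB and chemokines, 6 of 20 rose (13 adjusted over the list alone, camera adjusted p = 1.42e-26) at the medium and 7 of 20 rose (11 adjusted over the list alone, camera adjusted p = 2.12e-05) at the low dose. Between the high and the low dose, CXCL1 was higher by 1.24 ± 0.19, CYP1B1 by 0.82 ± 0.06 and ICAM1 by 0.82 ± 0.15 at the high dose, and HCG25 at -1.80 ± 0.36, THAP3 at -1.37 ± 0.29 and EIF4EBP3, which shares exons with a readthrough gene and is uncertain, at -1.33 ± 0.29 were lower. Aryl hydrocarbon receptor targets were higher at the high than at the low dose, where 6 of 11 rose (6 adjusted over the list alone, camera adjusted p = 5.50e-07). Genes of cytosolic ribosomal proteins stood above the vehicle at the low dose, where 37 of 72 rose (59 adjusted over the list alone, camera adjusted p = 2.72e-12, adjusted p = 0.432 with an estimated correlation). Of these genes 69 of 72 (72 adjusted over the list alone) were lower at the high than at the low dose (adjusted p = 0.342 with an estimated correlation). Nuclear genes of oxidative phosphorylation did likewise, with 20 of 38 above the vehicle at the low dose (adjusted p = 0.402 with an estimated correlation). These list results rest on low dose replicate 2, in which ribosomal protein genes took 10.7% of the counts, against 5.03 and 4.70% in the other low dose libraries and 4.63 to 5.41% in the vehicle. Without the 2 libraries that stand apart, both lists were called lower, not higher, than the vehicle at the low dose (camera adjusted p = 5.46e-10 and 0.0372). In that setting camera was run at the preset correlation only, so whether its calls hold with an estimated correlation is not known. Between the high and the low dose camera adjusted p was then 0.0169 for the ribosomal list, lower at the high dose, and 0.387 for oxidative phosphorylation. The test called 71 genes at the medium dose (38 higher, 33 lower), 2044 at the low dose (1454 higher, 590 lower) and 3552 between the high and the low dose (1173 higher, 2379 lower). The medium dose count moved to 42 and 28 without vehicle replicate 1 or 3 and 26 and 39 without medium dose replicate 1 or 3. The low dose count moved to 816, 1113 and 737 without vehicle replicate 1, 2 or 3 and 6334, 254 and 6522 without low dose replicate 1, 2 or 3. Between doses it moved to 1888, 1355 and 1988 without high dose replicate 1, 2 or 3 and 7380, 79 and 7383 without low dose replicate 1, 2 or 3. With only the 2 groups compared in the fit, edgeR called 0 genes at the low dose and 0 between doses, where DESeq2 called 2655 and 3966 in the fit of all libraries and edgeR had 5255 and 6380 at an unadjusted p under 0.05. Without the 2 libraries that stand apart the counts were 767 at the medium dose, 339 at the low dose (174 higher, 165 lower) and 113 between doses (65 higher, 48 lower). The excess of lower genes between doses thus did not remain in that fit. There the adjusted p was 0.213 for HCG25, 0.710 for THAP3 and 0.524 for EIF4EBP3.

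Soshiho-tang at the high dose (n = 2 against 3) gave the largest rise of any gene named in the comparisons with the vehicle that had replicates. CYP1A1, a cytochrome P450 enzyme induced through the aryl hydrocarbon receptor (ENSG00000140465, chromosome 15, 74719542 to 74725610 on GRCh38), rose by 8.36 ± 0.15 (adjusted p = 6.96e-35) on the log2 scale, from 0.502 ± 0.181 to 167 ± 5.92 CPM. CYP1B1 (ENSG00000138061, chromosome 2, 38066973 to 38109902) rose by 3.02 ± 0.07 and ALDH1A3 (ENSG00000184254, chromosome 15, 100877714 to 100916626) by 2.21 ± 0.07. Of aryl hydrocarbon receptor targets 10 of 11 rose (10 adjusted over the list alone, camera adjusted p = 3.54e-37). Of NRF2 targets, genes of the antioxidant response, 23 of 28 rose (24 adjusted over the list alone, camera adjusted p = 6.47e-39). These included SLC7A11 at 1.4 ± 0.11, the heme oxygenase HMOX1 at 1.16 ± 0.11, GCLM at 1.12 ± 0.09 and the aldo-keto reductase AKR1B10 at 1.06 ± 0.09. CXCL1 rose by 3.36 ± 0.22, CXCL8 by 1.70 ± 0.14, PI3 by 1.95 ± 0.19 and LRRN4 by 1.90 ± 0.23. Of the genes for NF-kB and chemokines 13 of 20 rose (15 adjusted over the list alone, camera adjusted p = 7.17e-20). Of ATF4 and integrated stress response genes, 12 of 30 rose (16 adjusted over the list alone, camera adjusted p = 3.50e-09). Leading were the amino acid transporter subunit SLC3A2 at 0.62 ± 0.09 and TRIB3 at 0.59 ± 0.09. Of cholesterol synthesis genes, 12 of 26 rose (18 adjusted over the list alone, camera adjusted p = 9.32e-16). Among them were STARD4 at 0.62 ± 0.09 and squalene epoxidase SQLE at 0.48 ± 0.04. Of hypoxia and glycolysis genes, 4 of 28 rose (7 adjusted over the list alone, camera adjusted p = 1.66e-05). Rising members were the glucose transporter SLC2A1 at 0.70 ± 0.04 and PFKP at 0.54 ± 0.08.

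Genes of secretory and stem cell identity fell at the high dose of Soshiho-tang. Of goblet and secretory cell genes, 7 of 17 fell (10 adjusted over the list alone, camera adjusted p = 1.04e-09). Lower were ATOH1, a transcription factor of the secretory lineage, at -1.33 ± 0.17, BCAS1 at -0.96 ± 0.06, SYTL2 at -0.94 ± 0.15 and CREB3L1 at -0.88 ± 0.15. Of Wnt and intestinal stem cell genes, 6 of 16 fell (9 adjusted over the list alone, camera adjusted p = 8.12e-07). Falling members were the ephrin receptor EPHB3 at -0.86 ± 0.12, SP5 at -0.69 ± 0.11 and PROM1 at -0.58 ± 0.11. The largest single falls were those of CD200 (ENSG00000091972, chromosome 3, 112332347 to 112362812) at -2.0 ± 0.18 (adjusted p = 3.93e-11), the sulfotransferase CHST3 at -1.61 ± 0.23, the GABA receptor subunit GABRP at -1.55 ± 0.10, the epithelial NADPH oxidase NOX1 at -1.51 ± 0.10, ANXA13 at -1.36 ± 0.09 and SPEG at -1.33 ± 0.16. Immediate early genes went both ways, 8 higher and 3 lower of 28 (13 and 4 adjusted over the list alone, camera adjusted p = 0.000145, adjusted p = 0.0980 with an estimated correlation). Members that changed included DUSP5 at 1.05 ± 0.13, EREG at 0.93 ± 0.09 and CCN2 at -0.98 ± 0.18. These values include the library labelled Soshiho-tang high dose replicate 3, which held HBB at 3.36 CPM. By edgeR, 1340 of 16890 genes passed (705 higher, 635 lower), 83 at least 2-fold higher and 96 at least 2-fold lower. The count was 678 without high dose replicate 3. Leaving out the 2 libraries that stand apart, which leaves 1 library assumed to vary like the other groups, 2150 genes passed, 987 of these 1340 among them.

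The rise of CYP1A1 was graded over the doses of Soshiho-tang, at 3.09 ± 0.18 for the medium (adjusted p = 6.47e-16) and 1.27 ± 0.22 for the low dose (adjusted p = 0.0135) against the vehicle (n = 2 against 3). Between the high and the low dose (n = 2 and 2), CYP1A1 differed by 7.09 ± 0.16, CYP1B1 by 2.49 ± 0.08 and CXCL1 by 2.31 ± 0.24, all higher at the high dose. GABRP at -1.66 ± 0.11, CHST3 at -1.60 ± 0.25 and NOX1 at -1.59 ± 0.11 were lower. At the high dose 24 of 28 NRF2 targets were higher than at the low dose (24 adjusted over the list alone, camera adjusted p = 6.03e-40). So were 15 of 28 immediate early genes, with 2 lower (20 and 3 adjusted over the list alone, camera adjusted p = 4.93e-13). Interferon response genes were lower at the high dose, 11 of 36 (13 adjusted over the list alone, camera adjusted p = 8.67e-10). The test called 40 genes at the medium dose (25 higher, 15 lower), 17 at the low dose (7 higher, 10 lower) and 1063 between the high and the low dose (550 higher, 513 lower). The medium dose count moved to 16 without vehicle replicate 3 and 14 and 12 without medium dose replicate 2 or 3. The low dose count moved to 39, 10 and 8 without vehicle replicate 1, 2 or 3 and 4 and 2 without low dose replicate 2 or 3. Between doses it moved to 562 and 498 without low dose replicate 2 or 3 and 516 without high dose replicate 3. The medium and low dose counts without the 2 libraries that stand apart were 294 and 326.

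**Figure D1:**
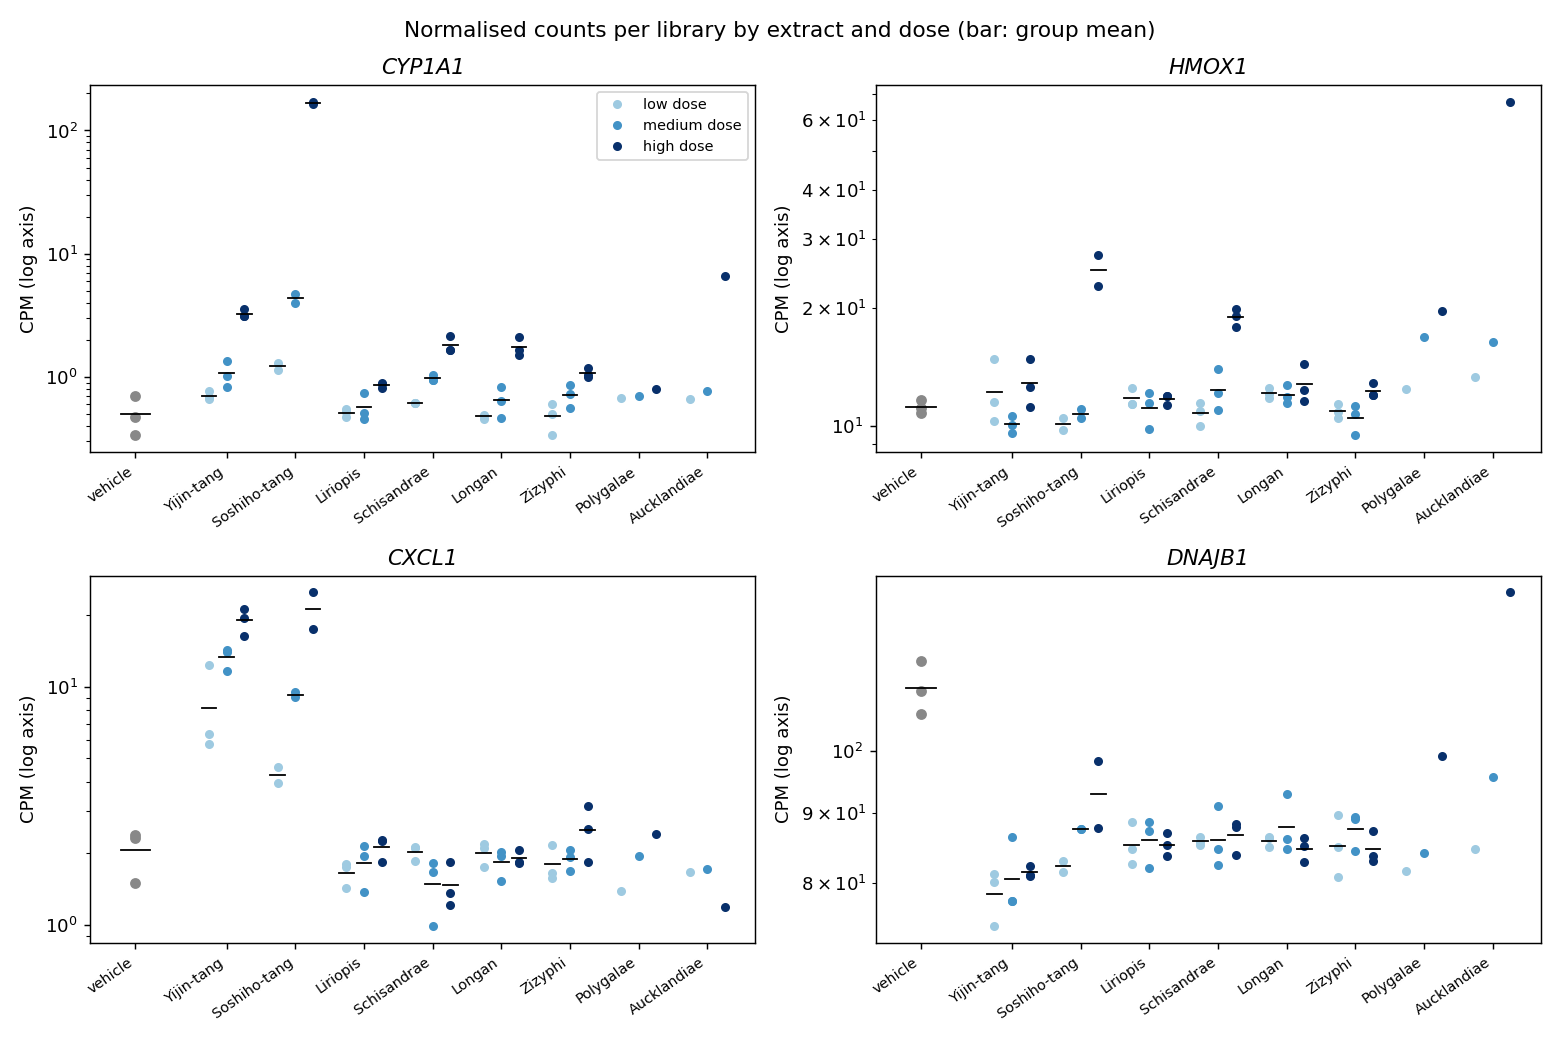
Levels of CYP1A1, HMOX1, CXCL1 and DNAJB1 in each library, in CPM on a log axis, by extract and dose, with the 3 vehicle libraries beside them. CYP1A1 averaged 167 CPM at the high dose of Soshiho-tang and 0.502 CPM in the vehicle.

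Both decoctions belong to library set 8 and were compared at 500 µg/mL (n = 3 Yijin-tang against 2 Soshiho-tang). CYP1A1 was lower with Yijin-tang, at -5.68 ± 0.12 (adjusted p = 1.19e-31), as were CYP1B1 at -2.16 ± 0.07, ALDH1A3 at -1.54 ± 0.07 and the organic cation transporter SLC22A3 at -1.30 ± 0.11. GABRP at 1.35 ± 0.10, the interferon-induced GTPase MX1 at 1.34 ± 0.28, NOX1 at 1.32 ± 0.11 and CHST3 at 1.28 ± 0.23 were higher with Yijin-tang. Lower with Yijin-tang were 17 of 28 NRF2 targets (21 adjusted over the list alone, camera adjusted p = 1.08e-28). So were 15 of 26 cholesterol synthesis genes (21 adjusted over the list alone, camera adjusted p = 2.15e-27), and 10 of 30 ATF4 genes (17 adjusted over the list alone, camera adjusted p = 1.02e-15). Of interferon response genes 11 of 36 were higher with Yijin-tang (19 adjusted over the list alone, camera adjusted p = 3.35e-15). For NF-kB and chemokines the list had a camera adjusted p = 0.0338, adjusted p = 0.0738 with an estimated correlation. Between the decoctions, 630 of 16890 genes passed (275 higher, 355 lower), and 288 without Soshiho-tang high dose replicate 3, which is the library that held HBB at 3.36 CPM. With single libraries left out, the highest adjusted p was 0.134 for MX1 and 0.0642 for CHST3.

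Schisandrae Fructus at the high dose (n = 3 against 3) raised NRF2 targets and aryl hydrocarbon receptor targets. HMOX1, which degrades heme (ENSG00000100292, chromosome 22, 35380361 to 35394214 on GRCh38), rose by 0.76 ± 0.10 (adjusted p = 6.29e-06), to 18.9 ± 0.964 CPM against 11.2 ± 0.424. SLC7A11 (ENSG00000151012, chromosome 4, 138164097 to 138242349) rose by 0.75 ± 0.10, GCLM by 0.64 ± 0.08 and AKR1B10 by 0.61 ± 0.08. Of the NRF2 targets 11 of 28 rose (17 adjusted over the list alone, camera adjusted p = 2.26e-28). Of aryl hydrocarbon receptor targets, 4 of 11 rose (6 adjusted over the list alone, camera adjusted p = 6.47e-14). They included CYP1A1, with a vehicle mean under 5 CPM, at 1.85 ± 0.19 and CYP1B1 at 0.73 ± 0.06. Other leading rises were those of the amino acid transporter SLC38A4 at 0.83 ± 0.15, CCDC78 at 0.80 ± 0.15 and CLIP4 at 0.68 ± 0.13. CCDC78 was higher in all 6 comparisons of library set 9 with the vehicle, low doses included. Of goblet and secretory cell genes, 1 of 17 fell (6 adjusted over the list alone, camera adjusted p = 1.38e-07), which was the secreted lectin REG4 (ENSG00000134193, chromosome 1, 119794018 to 119811660) at -0.65 ± 0.10. The other leading falls were those of SLC6A20 at -0.67 ± 0.11, SELENOW at -0.66 ± 0.15, NPY6R at -0.57 ± 0.14, ANXA13 at -0.53 ± 0.07 and the secreted BMP and Wnt antagonist SOSTDC1 at -0.48 ± 0.09. Cholesterol synthesis genes had a median of -0.08, and 1 of 26 fell (1 adjusted over the list alone, camera adjusted p = 0.000144), namely SQLE at -0.15 ± 0.04. Within library set 9, the high dose differed from the low dose in HMOX1 at 0.82 ± 0.10, AKR1B10 at 0.70 ± 0.08 and AKR1C2 at 0.86 ± 0.15, which were higher. SLC6A20 at -0.64 ± 0.11, SPEG at -0.56 ± 0.13 and SOSTDC1 at -0.53 ± 0.09 were lower. Of NRF2 targets, 8 of 28 were higher at the high than at the low dose (20 adjusted over the list alone, camera adjusted p = 7.49e-64).

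For Schisandrae Fructus at the high dose, 117 of 16890 genes passed (74 higher, 43 lower) by edgeR against the vehicle, 80 passed at the medium and 27 at the low dose, and 32 between the high and the low dose (20 higher, 12 lower). The high dose count moved to 49 without vehicle replicate 3 and 67 and 51 without high dose replicate 2 or 3. At the medium dose it moved to 29 and 14 without vehicle replicate 2 or 3 and 23 and 41 without medium dose replicate 1 or 3. The low dose count moved to 57 and 5 without vehicle replicate 1 or 3 and 17, 13 and 9 without low dose replicate 1, 2 or 3. Between doses it moved to 19, 17 and 20 without high dose replicate 1, 2 or 3 and 21 and 19 without low dose replicate 2 or 3. Without the 2 libraries that stand apart the counts were 1071, 1005, 812 and 90. The highest adjusted p with single libraries left out was 0.0859 for CLIP4, 0.122 for SELENOW and 0.331 for NPY6R against the vehicle. Between doses it was 0.108 for SLC6A20 and 0.611 for SPEG. AKR1B10 and AKR1C2 have closely related copies, between which the counting could split reads, and are uncertain.

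Liriopis seu Ophiopogonis Tuber at the high dose (n = 3 against 3) raised RTEL1-TNFRSF6B, a readthrough transcript that shares exons with its neighbours, by 0.73 ± 0.16, CCDC78 (ENSG00000162004, chromosome 16, 722582 to 726954 on GRCh38) by 0.65 ± 0.15 (adjusted p = 0.0231) and MAMDC4 by 0.65 ± 0.15. Also up were WDR90 by 0.63 ± 0.13, MEGF6 by 0.61 ± 0.14 and EME2, a subunit of a DNA endonuclease, by 0.61 ± 0.13. The largest falls were those of the ubiquitin ligase RNF19B at -0.40 ± 0.06, CCDC117 at -0.38 ± 0.07, the heat shock gene DNAJB1 at -0.38 ± 0.05, JMJD6 at -0.31 ± 0.07, SKA1, which joins kinetochores to microtubules, at -0.31 ± 0.06 and the chaperone HSPA8 at -0.30 ± 0.05. DNAJB1 and HSPA8 fell in all 18 comparisons with the vehicle. No NRF2 target rose at the high dose (0 of 28, 1 adjusted over the list alone, camera adjusted p = 0.933). Aryl hydrocarbon receptor targets had a median of 0.09, and 0 of 11 rose (2 adjusted over the list alone, camera adjusted p = 0.0127, adjusted p = 0.0544 with an estimated correlation). Between the high and the low dose, 0 genes passed by edgeR, with 320 at an unadjusted p under 0.05 and 2 by DESeq2. Aryl hydrocarbon receptor targets as a list were higher at the high than at the low dose (camera adjusted p = 5.20e-09), with a median of 0.11. Against the vehicle 76 of 16890 genes passed (61 higher, 15 lower) at the high dose, 64 at the medium and 83 at the low dose. The high dose count moved to 30 and 18 without vehicle replicate 2 or 3 and 35 and 20 without high dose replicate 1 or 3. At the medium dose it moved to 115, 29 and 7 without vehicle replicate 1, 2 or 3 and 22, 22 and 24 without medium dose replicate 1, 2 or 3. At the low dose it moved to 162, 18 and 10 without vehicle replicate 1, 2 or 3 and 17 and 14 without low dose replicate 2 or 3. The 3 counts without the 2 libraries that stand apart were 841 (481 higher, 360 lower), 967 and 1075. With single libraries left out, the highest adjusted p was 0.268 for RTEL1-TNFRSF6B, 0.273 for CCDC78, 0.315 for MAMDC4, 0.214 for WDR90, 0.237 for MEGF6, 0.205 for EME2, 0.0813 for CCDC117, 0.218 for JMJD6 and 0.0855 for SKA1.

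At 500 µg/mL, Liriopis seu Ophiopogonis Tuber and Schisandrae Fructus (n = 3 and 3, library set 9) differed in NRF2 targets and aryl hydrocarbon receptor targets. HMOX1 at -0.70 ± 0.10 (adjusted p = 0.000122), AKR1B10 at -0.60 ± 0.08, CYP1B1 at -0.58 ± 0.06 and ALDH3A1 at -0.44 ± 0.07 were lower with Liriopis seu Ophiopogonis Tuber. SOSTDC1 at 0.44 ± 0.09, the dipeptidase DPEP1 at 0.33 ± 0.06, SLC7A7 at 0.27 ± 0.06 and LOXL4 at 0.26 ± 0.05 were higher. Lower with Liriopis seu Ophiopogonis Tuber were 4 of 28 NRF2 targets (20 adjusted over the list alone, camera adjusted p = 7.42e-54) and 4 of 11 aryl hydrocarbon receptor targets (5 adjusted over the list alone, camera adjusted p = 9.58e-16). Between these extracts, 16 of 16890 genes passed (6 higher, 10 lower). The count moved to 9 and 7 without Liriopis seu Ophiopogonis Tuber high dose replicate 1 or 3 and 10 and 10 without Schisandrae Fructus high dose replicate 1 or 3. In the fit without the 2 libraries that stand apart 73 genes passed, 16 of these 16 among them. With single libraries left out, the highest adjusted p was 0.305 for SOSTDC1, 0.0976 for DPEP1, 0.271 for SLC7A7, 0.271 for LOXL4 and 0.0564 for ALDH3A1.

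Longan Arillus at the high dose (n = 3 against 3) raised CYP1B1 by 0.56 ± 0.06 (adjusted p = 5.71e-07), to 68.9 ± 2.35 CPM against 46.7 ± 1.29, and ALDH1A3 by 0.52 ± 0.07. Of aryl hydrocarbon receptor targets, 3 of 11 rose (5 adjusted over the list alone, camera adjusted p = 2.03e-14), the remaining gene being CYP1A1 at 1.79 ± 0.19, from a vehicle mean under 5 CPM. The NRF2 targets SLC7A11 and GCLM rose by 0.51 ± 0.10 and 0.43 ± 0.08, and of the list 2 of 28 rose (3 adjusted over the list alone, camera adjusted p = 3.13e-06, adjusted p = 0.0556 with an estimated correlation). ZNF367 rose by 0.34 ± 0.07 and the zinc exporter SLC30A1 by 0.33 ± 0.07. The 5 genes that fell were DNAJB1 at -0.39 ± 0.05, CCDC117 at -0.39 ± 0.07, RNF19B at -0.31 ± 0.06, HSPA8 at -0.30 ± 0.05 and HSPH1 at -0.28 ± 0.06. Of these, DNAJB1 and HSPA8 fell in all 18 comparisons with the vehicle and HSPH1 in 11. Between the high and the low dose, CYP1B1 at 0.55 ± 0.06 and ALDH1A3 at 0.50 ± 0.07 were higher at the high dose. Of aryl hydrocarbon receptor targets 3 of 11 were higher (5 adjusted over the list alone, camera adjusted p = 3.53e-16). Against the vehicle, 13 of 16890 genes passed (8 higher, 5 lower) at the high dose, 2 at the medium and 18 at the low dose, and 3 passed between the high and the low dose. The high dose count moved to 8 and 4 without vehicle replicate 1 or 3 and 6 and 7 without high dose replicate 1 or 3. At the medium dose it moved to 4 and 1 without vehicle replicate 2 or 3 and 1 without medium dose replicate 2. At the low dose it moved to 10, 31 and 1 without vehicle replicate 1, 2 or 3 and 1 and 11 without low dose replicate 1 or 3. Without the 2 libraries that stand apart the counts were 384, 160, 820 and 943. With single libraries left out, the highest adjusted p was 0.163 for SLC7A11, 0.235 for GCLM, 0.305 for ZNF367, 0.518 for SLC30A1, 0.167 for CCDC117, 0.235 for RNF19B, 0.0953 for HSPA8 and 0.347 for HSPH1.

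Zizyphi Semen at the high dose (n = 3 against 3) raised aryl hydrocarbon receptor targets, of which 4 of 11 rose (5 adjusted over the list alone, camera adjusted p = 4.20e-07). ALDH1A3 rose by 0.39 ± 0.07 (adjusted p = 0.00394), ALDH3A1 by 0.36 ± 0.07, CYP1B1 by 0.35 ± 0.06 and CYP1A1, from a vehicle mean under 5 CPM, by 1.07 ± 0.21. Outside that list C1orf159 rose by 0.31 ± 0.07, LOXL4 by 0.30 ± 0.05 and GCLC by 0.27 ± 0.05. The mitotic kinesin CENPE (ENSG00000138778, chromosome 4, 103105806 to 103198409 on GRCh38) had the largest fall, at -0.83 ± 0.15 (adjusted p = 0.00589), or 37.2 ± 2.94 CPM against 66.2 ± 5.02. Next came the golgin GOLGA4 at -0.55 ± 0.10, PPP2R5B at -0.50 ± 0.11, CCDC117 at -0.46 ± 0.07, BMP2 at -0.43 ± 0.08 and ANXA13 at -0.40 ± 0.07. CENPE was the 1 gene of 28 in the list of cell cycle G2/M genes that changed (camera adjusted p = 0.107). Within library set 10, CENPE at -0.85 ± 0.15, the anchoring protein AKAP9 at -0.72 ± 0.14 and GOLGA4 at -0.59 ± 0.10 were lower at the high than at the low dose. ALDH3A1 at 0.38 ± 0.07, ALDH1A3 at 0.36 ± 0.07 and CYP1B1 at 0.31 ± 0.06 were higher. Against the vehicle, 27 of 16890 genes passed (8 higher, 19 lower) at the high dose, 5 at the medium and 6 at the low dose, and 9 passed between the high and the low dose. The high dose count moved to 7 without vehicle replicate 3 and 10, 12 and 12 without high dose replicate 1, 2 or 3. At the medium dose it moved to 8 and 1 without vehicle replicate 1 or 3 and 2, 1 and 1 without medium dose replicate 1, 2 or 3. The low dose count moved to 1 without vehicle replicate 3 and 1, 1 and 3 without low dose replicate 1, 2 or 3. Between doses it moved to 0, 3 and 2 without high dose replicate 1, 2 or 3 and 0, 5 and 0 without low dose replicate 1, 2 or 3. Without the 2 libraries that stand apart the counts were 546, 134, 270 and 42. The highest adjusted p with single libraries left out was 0.0801 for ALDH1A3, 0.229 for ALDH3A1, 0.0571 for CYP1B1, 0.339 for C1orf159, 0.0685 for LOXL4, 0.123 for GCLC, 0.0963 for CENPE, 0.104 for GOLGA4, 0.294 for PPP2R5B, 0.156 for BMP2, 0.149 for ANXA13 and 0.386 for CYP1A1 against the vehicle. Between doses it was 0.279 for ALDH3A1, 0.367 for ALDH1A3, 0.497 for CYP1B1, 0.246 for CENPE, 0.468 for AKAP9 and 0.200 for GOLGA4.

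Longan Arillus and Zizyphi Semen at 500 µg/mL (n = 3 and 3, library set 10) differed in 4 genes, 3 higher and 1 lower with Longan Arillus. TXNIP, a thioredoxin-binding protein that responds to glucose, was lower with Longan Arillus at -0.43 ± 0.06 (adjusted p = 4.33e-05), and GOLGA4 was higher at 0.52 ± 0.10 (adjusted p = 0.0347). Of the glucose-sensing genes 1 of 7 was lower (1 adjusted over the list alone, camera adjusted p = 0.000410), and of LXR targets 1 of 8 was higher (1 adjusted over the list alone, camera adjusted p = 0.000410). The count moved to 2 and 2 without Zizyphi Semen high dose replicate 1 or 3 and 2 without Longan Arillus high dose replicate 3, and to 9 without the 2 libraries that stand apart. For GOLGA4 the highest adjusted p with single libraries left out was 0.915.

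As a list, heat shock genes lay below the vehicle at nearly every dose of every replicated extract, though not every member fell. DNAJB1, a co-chaperone of HSP70 (ENSG00000132002, chromosome 19, 14514770 to 14529770 on GRCh38), and HSPA8, the constitutive HSP70 (ENSG00000109971, chromosome 11, 123057489 to 123063230), fell in 18 of 18 comparisons with the vehicle. DNAJB1 had log2 values from -0.50 to -0.26 and HSPA8 from -0.45 to -0.18. HSPH1 fell in 11, HSPA1B in 8 and HSPA1A in 6, the last pair being near-identical copies that are uncertain. CHORDC1 fell in 4, BAG3 and STIP1 in 1 each, and the other 9 of the 17 members in none, of which HSPD1 rose in 1. The list was called lower in 17 of the 18 comparisons, 16 of them with an estimated correlation. The exception was Soshiho-tang at the high dose (camera adjusted p = 0.290, median -0.03). CYP1B1 and ALDH1A3 each rose in 9 of the 18 comparisons, CYP1A1 in 8, SLC7A11 in 7, and CXCL1, CXCL8 and CCL20 in 5 each. These comparisons share the 3 vehicle libraries. In 8 simulations of unchanged groups against shared simulated controls, no gene fell in more than 1 comparison or rose in more than 1. In 1 simulation, however, the heat shock median lay below 0 in 17 of the 18, down to -0.07, so the shared sign alone carries little weight. Each gene was drawn independently there, with no effect of a library or library set. The simulations can therefore understate how often genes recur and how far genes that vary together move.

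Over the 18 comparisons with the vehicle, 178 of 540 list tests were called, 72 of them with an estimated correlation. With an estimated correlation, aryl hydrocarbon receptor targets were called higher in 9 comparisons, the genes for NF-kB and chemokines and those of DNA replication and S phase in 6 each, drug metabolism and transport genes in 4, NRF2 targets and interferon response genes in 3 each, and ATF4 genes in 2. Goblet and secretory cell genes were called lower in 6, immediate early genes and genes of the unfolded protein response of the endoplasmic reticulum in 3 each, the glucose-sensing genes in 2 and mitochondrially encoded transcripts in 2. In that setting 1 comparison each was called for hypoxia and glycolysis, ribosome biogenesis, fatty acid oxidation with PPAR targets, the unfolded protein response (all higher) and Wnt and intestinal stem cell genes (lower), and cholesterol synthesis was called once in each direction. Cytosolic ribosomal protein genes were called lower in 15 comparisons and higher in 1, mitochondrially encoded transcripts lower in 17 and G2/M genes lower in 9 at the preset correlation, against 0, 2 and 0 with an estimated correlation. At the preset correlation immediate early genes were called lower in 16 and higher in 1, and unfolded protein response genes lower in 10 and higher in 1. Nuclear oxidative phosphorylation, fatty acid synthesis, LXR target and histone genes had calls at the preset correlation only, in 8, 1, 1 and 3 comparisons. Targets of p53, absorptive colonocyte genes, metallothioneins, autophagy and lysosome genes and the hepatocyte and leukocyte markers had 0 calls in either direction, and the fibroblast and endothelial markers had too few tested genes for a test.

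**Figure D2:**
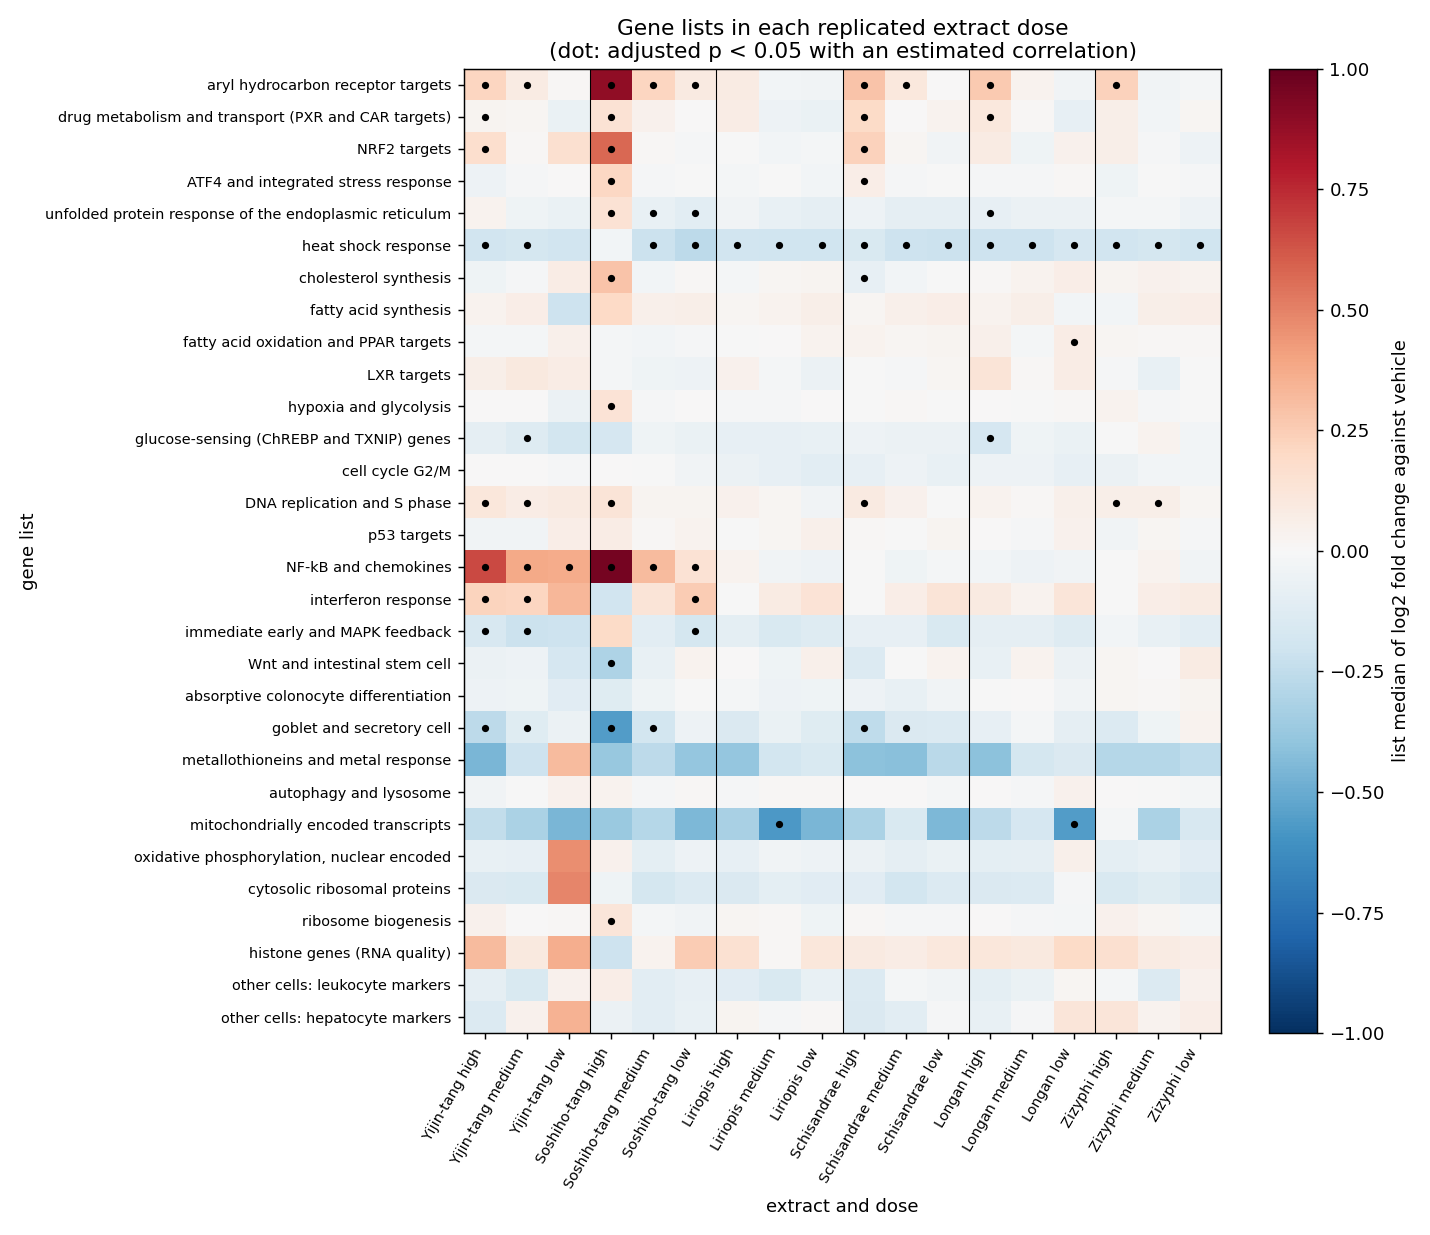
Median log2 fold change against the vehicle of each gene list (vertical axis) in each replicated extract and dose (horizontal axis), on a colour scale, with dots where the list was called with an estimated correlation. Aryl hydrocarbon receptor targets had a median of 0.89 and NRF2 targets of 0.57 at the high dose of Soshiho-tang.

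Fold changes of the high against the low dose were compared between the 6 replicated extracts across 16890 genes, which are not independent replicates. Aryl hydrocarbon receptor targets were called higher at the high than at the low dose in 6 of the 6 extracts, 6 of them with an estimated correlation (adjusted p at most 5.73e-05). The list medians ran from 0.11 for Liriopis seu Ophiopogonis Tuber to 0.80 for Soshiho-tang, and the comparisons lie within library sets and share no library. Over all genes the median Pearson correlation between the 15 pairs of extracts was 0.0354. The highest was 0.283 for Yijin-tang with Longan Arillus (Spearman 0.465), which was -0.0576 without the 2 libraries that stand apart. In that setting the highest was 0.220, for Yijin-tang with Schisandrae Fructus, against 0.117 with all libraries.

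**Figure D3:**
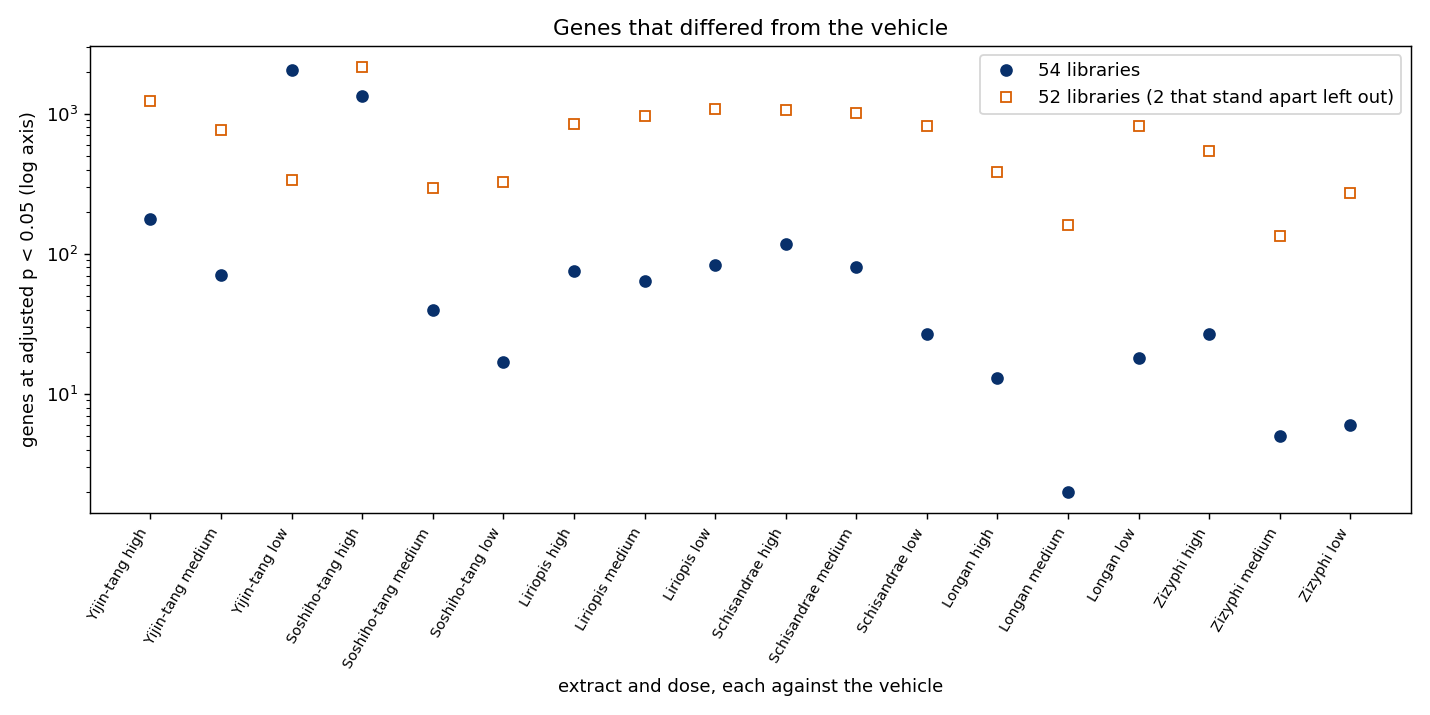
Number of genes called against the vehicle, on a log axis, for each replicated extract and dose, with all 54 libraries and with 52, leaving out those that stand apart. Yijin-tang at the low dose went from 2044 to 339 genes, and each other group had more genes called with 52 libraries.

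Aucklandiae Radix at 370 µg/mL had 1 library, so its differences from the vehicle mean (n = 3) have no replicate check and no p-value. The scaffold protein gene AHNAK2 (ENSG00000185567, chromosome 14, 104937244 to 104978357 on GRCh38) stood at 465 CPM against 7.45 ± 1.73 CPM, a log2 ratio of 5.97. The ratio was 6.21 for the cystatin CST1, 5.67 for CYP4F11, 5.32 for SPRR1B, a protein of the cornified envelope, 4.96 for the retinol dehydrogenase DHRS9 and 4.87 for SDCBP2. Among the lowest were -4.93 for SLC38A11 (ENSG00000169507, chromosome 2, 164896186 to 164955525), -4.56 for KCNJ3, -4.46 for CD200, -4.43 for COLCA1 and -4.20 for NOX1. Of NRF2 targets 28 of 28 were higher (median 1.4, percentile 100 among 10000 random lists matched on expression), with HMOX1 at 2.57 and SLC7A11 at 1.95, and 28 were higher at the medium (median 0.55, percentile 100) and 24 at the low dose (median 0.23, percentile 100). All 28 G2/M genes were lower (median -0.97, percentile 0), as were 30 of 32 genes of DNA replication (median -0.73, percentile 0) and 14 of 17 goblet and secretory cell genes (median -1.20, percentile 0). Of autophagy and lysosome genes 27 of 27 were higher (median 0.94, percentile 100), and of immediate early genes 22 of 28 (median 1.25, percentile 100). These lists did not all keep their direction at lower doses. Of G2/M genes 14 of 28 were lower at the medium dose (median 0.00, percentile 24.3) and 21 at the low dose (median -0.09, percentile 0.01). Of immediate early genes 13 of 28 were higher at the medium dose (median -0.01, percentile 34.5) and 10 at the low dose (median -0.06, percentile 1.35). Of DNA replication genes 24 of 32 were higher at the medium dose (median 0.08, percentile 98.9) and 23 at the low dose (median 0.07, percentile 99.6). Of goblet and secretory cell genes 14 of 17 were lower at the medium dose (median -0.28, percentile 0) and 13 at the low dose (median -0.05, percentile 11.6). Of autophagy and lysosome genes 20 of 27 were higher at the medium dose (median 0.12, percentile 99.9) and 13 at the low dose (median 0.00, percentile 45.1). In the high dose library 1366 of 10945 genes at 5 CPM or more lay at least 2-fold from the vehicle mean (771 higher, 595 lower), against 17 at the medium and 9 at the low dose. Each vehicle library against the mean of the others gave 15, 5 and 13. Endothelial marker genes summed to 152 CPM in the high dose library and 70.3 CPM at the medium dose, against 45.0 to 49.5 CPM in the vehicle and at most 62.4 CPM in the libraries of other extracts. In the median library 2 of the 8 markers reached 1 CPM, and ESAM at 43.9 CPM made up most of the sum. The sum thus need not mark endothelial cells. Of histone genes, a list kept as a sign of RNA quality, 11 of 14 were higher at the high dose (median 0.59, percentile 99.8), 6 of them at least 2-fold, while histone genes as a class held 0.0274% of the counts, the lowest share of all libraries (0.0400 to 0.0409% in the vehicle). What these shifts stem from was not tested.

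Polygalae Radix at 380 µg/mL, also with 1 library and no replicate check, showed smaller ratios. The autophagy receptor gene SQSTM1 (ENSG00000161011, chromosome 5, 179806398 to 179838078 on GRCh38) stood at 946 CPM against 357 ± 13.3 CPM in the vehicle (n = 3), a log2 ratio of 1.41. Higher too were UAP1L1 at 1.52, the nuclear receptor NR0B2 at 1.51, the protease PRSS22 at 1.39, the readthrough gene BCL2L2-PABPN1 at 1.35 and the pseudogene ZBTB45P1 at 3.33, the last with an SD of 3.56 around 4.10 CPM in the vehicle. Among the lower genes were PHGDH, which starts serine synthesis (ENSG00000092621, chromosome 1, 119648411 to 119744226), at -1.74, the asparagine synthetase ASNS at -1.49, the brush border protein villin VIL1 at -1.62, ALDH1A1 at -1.54, CKMT1A at -1.39 and the pseudogene LDHAP4 at -1.96. CKMT1A and both pseudogenes have near-identical copies, BCL2L2-PABPN1 shares exons with its neighbours, and these 4 are uncertain. All 38 nuclear oxidative phosphorylation genes (median -0.37, percentile 0) and all 28 G2/M genes (median -0.48, percentile 0) were lower, as were 16 of 17 goblet and secretory cell genes (median -0.50, percentile 0) and 16 of 17 heat shock genes (median -0.47, percentile 0.03). At the medium and low doses the number lower was, in this order, 37 (percentile 0) and 28 (percentile 0.15) for oxidative phosphorylation, 27 and 26 for G2/M, and 16 and 17 for heat shock (percentile 0 for each of these 4). The medians at these doses were -0.20 and -0.06 for oxidative phosphorylation, -0.20 and -0.12 for G2/M, and -0.25 and -0.24 for heat shock. Against the same vehicle libraries, the low doses of the replicated extracts had heat shock medians from -0.265 to -0.171. The lower heat shock genes at these doses were thus not particular to Polygalae Radix. The percentiles set 1 library against random lists of genes and do not measure the spread between libraries. Goblet and secretory cell genes were lower in 13 at the medium dose (percentile 0), but 10 of 17 were higher at the low dose (median 0.06, percentile 90.2). The number of genes at least 2-fold from the vehicle mean was 108 (28 higher, 80 lower), 23 at the medium and 8 at the low dose. In the high dose library hepatocyte marker genes summed to 212 CPM, against at least 287 CPM in every other library, and leukocyte marker genes to 969 CPM, against at least 1123. In the median library these sums rested largely on 1 gene each, SERPINA1 at 315 CPM and LYZ at 1405 CPM. They thus need not mark other cell types. Histone genes as a class held 0.0517% of the counts, the highest share of all libraries, and of the list 6 of 14 were higher (median -0.08, percentile 32.3), 4 of them at least 2-fold. The source of these shifts was not tested either.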

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

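Tests without the library labelled Yijin-tang low dose replicate 2 and the library labelled Soshiho-tang high dose replicate 3 were chosen after seeing the data, and the other alternatives were set beforehand. With RLE normalization all 27 counts of genes stayed within 1.5 times their value, and with the replicate block 26 of 27 did. The median correlation of the high against low dose fold changes over the 15 pairs of replicated extracts was 0.0354, and from 0.00475 to 0.0785 under its alternatives. The cause was not tested for the changes below, except where fewer libraries, or more genes without the filter, enter by construction. In comparisons that hold neither library that stands apart, leaving these out acts only through the spread, scaling and gene filter shared by all libraries. There every gene called with 54 libraries kept its call, as for Longan Arillus high against low dose (3 genes, then 943). Small counts with 54 libraries thus do not show that an extract had little effect.

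DESeq2 moved 18 of 27 counts of genes by more than 1.5 times: Yijin-tang 117 (medium), Soshiho-tang 39 (low), Liriopis seu Ophiopogonis Tuber 163 (high), 200 (medium), 198 (low), 2 (high against low), Schisandrae Fructus 218 (high), 145 (medium), 76 (low), Longan Arillus 37 (high), 11 (medium), 62 (low), 5 (high against low), Zizyphi Semen 55 (high), 11 (medium), 11 (low), Liriopis seu Ophiopogonis Tuber against Schisandrae Fructus 30, Longan Arillus against Zizyphi Semen 9. Without a filter on low counts 18 moved, with more genes tested: Yijin-tang 84 (high), 44 (medium), Soshiho-tang 865 (high), 22 (medium), 639 (high against low), Liriopis seu Ophiopogonis Tuber 32 (high), 39 (medium), 42 (low), Schisandrae Fructus 52 (high), 42 (medium), 17 (high against low), Longan Arillus 0 (medium), 11 (high against low), Zizyphi Semen 15 (high), 2 (medium), 4 (high against low), Liriopis seu Ophiopogonis Tuber against Schisandrae Fructus 9, Longan Arillus against Zizyphi Semen 7. With only the 2 groups in the fit 22 moved, with fewer libraries to estimate the spread: Yijin-tang 92 (high), 0 (low), 0 (high against low), Soshiho-tang 475 (high), 18 (medium), 4 (low), 285 (high against low), Liriopis seu Ophiopogonis Tuber 21 (high), 1 (medium), 50 (low), Schisandrae Fructus 17 (medium), 75 (high against low), Longan Arillus 5 (high), 5 (medium), 4 (low), 9 (high against low), Zizyphi Semen 3 (medium), 15 (low), 45 (high against low), Yijin-tang against Soshiho-tang 270, Liriopis seu Ophiopogonis Tuber against Schisandrae Fructus 42, Longan Arillus against Zizyphi Semen 15. Without the 2 libraries that stand apart 24 moved: Yijin-tang 1239 (high), 767 (medium), 339 (low), 113 (high against low), Soshiho-tang 2150 (high), 294 (medium), 326 (low), Liriopis seu Ophiopogonis Tuber 841 (high), 967 (medium), 1075 (low), Schisandrae Fructus 1071 (high), 1005 (medium), 812 (low), 90 (high against low), Longan Arillus 384 (high), 160 (medium), 820 (low), 943 (high against low), Zizyphi Semen 546 (high), 134 (medium), 270 (low), 42 (high against low), Liriopis seu Ophiopogonis Tuber against Schisandrae Fructus 73, Longan Arillus against Zizyphi Semen 9. Of 178 list calls, 72 held with an estimated correlation. Of 76 list calls at high doses against the vehicle (adjusted p in brackets), calls were lost for goblet and secretory cell (Liriopis seu Ophiopogonis Tuber, 0.0551; Zizyphi Semen, 0.0581) and oxidative phosphorylation, nuclear encoded (Schisandrae Fructus, 0.0527) with the replicate block, for oxidative phosphorylation, nuclear encoded (Schisandrae Fructus, 0.0503) and goblet and secretory cell (Zizyphi Semen, 0.0511) with a prior count of 0.5, and for glucose-sensing (ChREBP and TXNIP) genes (Yijin-tang, 0.0737; Soshiho-tang, 0.0762), mitochondrially encoded transcripts (Soshiho-tang, 0.368) and interferon response (Longan Arillus, 0.107) without the 2 libraries that stand apart. Of the list calls named at other doses or between extracts, those of ribosomal proteins and oxidative phosphorylation at the low dose of Yijin-tang reversed without these 2 libraries, and those of oxidative phosphorylation between its high and low dose (adjusted p = 0.387) and of NF-kB and chemokines between Yijin-tang and Soshiho-tang (adjusted p = 0.350) were lost.

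With each library of the compared groups left out in turn, and a lone remaining library assumed to vary like the other groups, the counts ran over these ranges. Vehicle and dose comparisons: Yijin-tang 80 to 194 (high), 26 to 69 (medium), 254 to 6522 (low), 79 to 7383 (high against low). Soshiho-tang 678 to 1195 (high), 12 to 30 (medium), 2 to 39 (low), 498 to 996 (high against low). Liriopis seu Ophiopogonis Tuber 18 to 114 (high), 7 to 115 (medium), 10 to 162 (low), 0 to 0 (high against low). Schisandrae Fructus 49 to 142 (high), 14 to 119 (medium), 5 to 57 (low), 17 to 22 (high against low). Longan Arillus 4 to 16 (high), 1 to 4 (medium), 1 to 31 (low), 3 to 3 (high against low). Zizyphi Semen 7 to 25 (high), 1 to 8 (medium), 1 to 6 (low), 0 to 5 (high against low). Between extracts: Yijin-tang against Soshiho-tang 288 to 593, Liriopis seu Ophiopogonis Tuber against Schisandrae Fructus 7 to 12, Longan Arillus against Zizyphi Semen 2 to 3.

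With the replicate number as a block, Longan Arillus 7 (medium) genes were called, where the count had moved by more than 1.5 times. Within the library set the block gave Yijin-tang 1 (high against low), Soshiho-tang 101 (high against low), Liriopis seu Ophiopogonis Tuber 1 (high against low), Schisandrae Fructus 82 (high against low), Longan Arillus 765 (high against low), Zizyphi Semen 26 (high against low), Yijin-tang against Soshiho-tang 46, Liriopis seu Ophiopogonis Tuber against Schisandrae Fructus 79, Longan Arillus against Zizyphi Semen 11. In Schisandrae Fructus medium dose against vehicle, where replicate numbers appeared to pair the libraries, the count was 80, and 84 with the block. Of 54 libraries, 34 correlated best with those of their own number, which is more than numbers without meaning would give on average. This count was not tested, and its libraries are not independent. A replicate effect shared by several groups, which the main fit did not model, is thus not excluded.

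Among genes drawn by the rule for named genes, 5 lost and 212 held their call with DESeq2, 64 without the filter, 80 (against 136 that held) with only the 2 groups, 3 with the replicate block and 15 without the 2 libraries that stand apart, and 0 reversed. Of these, the following are named in the text. Lost with DESeq2: CCL20 (Yijin-tang high); PPP2R5B (Zizyphi Semen high). Lost with the replicate block: NPY6R (Schisandrae Fructus high); SPEG (Schisandrae Fructus high against low). Lost without the 2 libraries that stand apart: HCG25, THAP3 and EIF4EBP3 (Yijin-tang high against low); MX1 (Yijin-tang against Soshiho-tang). Lost without the filter: IFIT5 (Yijin-tang high); MEGF6, JMJD6, SKA1 and HSPA8 (Liriopis seu Ophiopogonis Tuber high); NPY6R and SQLE (Schisandrae Fructus high); ZNF367, SLC30A1, CCDC117, RNF19B, HSPA8 and HSPH1 (Longan Arillus high); ALDH1A3, ALDH3A1, CYP1B1, C1orf159, LOXL4, GCLC, PPP2R5B, BMP2, ANXA13 and CYP1A1 (Zizyphi Semen high); SPEG (Schisandrae Fructus high against low); ALDH3A1, ALDH1A3 and CYP1B1 (Zizyphi Semen high against low); SOSTDC1, DPEP1, SLC7A7 and LOXL4 (Liriopis seu Ophiopogonis Tuber against Schisandrae Fructus). Lost with only the 2 groups: FAM131B, MYCL, OSR1 and IFIT5 (Yijin-tang high); RTEL1-TNFRSF6B, CCDC78, MAMDC4, WDR90, MEGF6, RNF19B, JMJD6, SKA1 and HSPA8 (Liriopis seu Ophiopogonis Tuber high); CLIP4, SLC6A20, NPY6R and SQLE (Schisandrae Fructus high); SLC7A11, GCLM, ZNF367, SLC30A1, CCDC117, RNF19B, HSPA8, HSPH1 and CYP1A1 (Longan Arillus high); ALDH1A3, ALDH3A1, C1orf159, LOXL4, GCLC, PPP2R5B, BMP2, ANXA13 and CYP1A1 (Zizyphi Semen high); CXCL1, CYP1B1, ICAM1, HCG25, THAP3 and EIF4EBP3 (Yijin-tang high against low); SPEG (Schisandrae Fructus high against low); SLC7A7 (Liriopis seu Ophiopogonis Tuber against Schisandrae Fructus). For the genes drawn for Polygalae Radix and Aucklandiae Radix, 4 of 24 ratios moved beyond the SD of the vehicle libraries with a prior count of 0.5, and 0 under the other settings. Of 33 list medians of these extracts over their doses, 0 moved beyond that SD with a prior count of 0.5, 1 with RLE and 7, 7 and 3 without vehicle replicate 1, 2 or 3. None of the medians beyond that SD changed sign.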

Other observations

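The tests of heat shock genes by dose, of the library sets for heat shock genes and of library set 9, and the bound used in the length test, were chosen after the results were seen. The patterns below were noticed in these data and tested on the same data, so each explanation is a hypothesis.

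As a list, heat shock genes lay below the vehicle at nearly every dose. A fall that deepens with dose was argued against, since in 0 of 6 replicated extracts the list was called lower at the high than at the low dose (camera adjusted p under 0.05). The list median against the vehicle was lower at the high dose in 2 of the 6, by at most 0.04. A change with dose in the other direction is not excluded: for Soshiho-tang the median went from -0.265 at the low to -0.0258 at the high dose (camera adjusted p = 1.07e-07), and the list was called higher at the high dose for Schisandrae Fructus too (camera adjusted p = 0.0381, adjusted p = 0.320 with an estimated correlation). Also argued against was 1 vehicle library with high heat shock genes, since against single vehicle libraries the median over low dose groups of the list medians was -0.0915, -0.229 and -0.247 against replicate 1, 2 and 3. The size thus depended on the vehicle library. Over single low dose groups the medians ran from -0.158 to -0.0687 against vehicle replicate 1, the last of these within the range of the simulations of unchanged groups (lowest -0.0704). That range is not like for like, since it came from comparisons with 3 simulated controls, and medians against 1 library vary more. It can also be too narrow because the simulations drew each gene independently. Which of the medians against vehicle replicate 1 lie beyond such variation thus cannot be told from it. The mean list median was -0.207 at the low and -0.160 at the high dose. A difference between the vehicle library set and the extract library sets, and an effect complete at the lowest dose, cannot be told apart, since no vehicle library lies in an extract set. A difference in DMSO cannot be told apart from either, since its percentage was found for the vehicle only.

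The library labelled Yijin-tang low dose replicate 2 stands apart, and a shift of reads by transcript length is a candidate explanation. Its deviations correlated with transcript length at a Spearman rho of -0.630, against a size of at most 0.461 in 45 libraries of other groups. The bound set before the result was the highest of all other libraries, 0.635, which this library did not pass. That bound was replaced because it came from replicates measured against this library itself. Opposite strand counting (ratio of shares 1.5) and RNA of other cells (highest ratio of marker sums 1.28) fell between their bounds and stay open, as do a mislabelled library and a biological difference, which were not tested. The 1.28 was that of leukocyte markers, whose sum of 2028 CPM held 2014 CPM of LYZ. LYZ had a median of 1405 CPM in the other libraries, so this sum in effect measured 1 gene of the cell line. It cannot decide on RNA of other cells.

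In library set 9, 35 genes, such as CCDC78, MAMDC4 and WDR90, were higher than in the vehicle at 4 or more of 6 doses, with a median GC content of 65.0% against 48.7% for all genes. Deviations of vehicle replicates 1, 2 and 3 from the other vehicle libraries correlated with GC content at a Spearman rho of 0.363, -0.599 and 0.138. A correction that removes the average GC trend of each library left the 35 genes at a median log2 fold change of 0.321 (SD over genes 0.137), from 0.371 (0.143). Of these, 14 still had that many calls. The average trend thus did not account for most of the rise. As evidence against a GC content bias as the whole cause this is weak, since these genes were chosen for being high, which favours a rise that outlasts the correction. Of 178 calls of these genes the correction ended 93, all with a smaller fold and 60 also with a larger standard error. Over these the median log2 fold change went from 0.366 to 0.282 and the median standard error from 0.0794 to 0.0781. Calls of all genes in these comparisons went from 447 to 323, a smaller net fall in share than among these genes. That contrast cannot be weighed, since the 35 genes were chosen by their calls before the correction. GC content as part of the cause is not excluded. For vehicle libraries apart from all extract library sets alike, the median in the low dose groups of Soshiho-tang, Longan Arillus and Zizyphi Semen was 0.131, under the bound set by 0.362 in set 9, but these groups ran from 0.104 to 0.204, a spread that leaves this open. The low dose of Yijin-tang, which holds a library that stands apart, was left out of this test. For a difference between library set 9 and the vehicle library set, 0 of these genes differed between high and low dose by edgeR, so that the set and an effect complete at the lowest dose cannot be told apart.

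With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. In these comparisons 1 of 10 splits, the real one, gave as many genes, and the real count and the highest other were: Yijin-tang high dose against vehicle 177 and 0, Yijin-tang medium dose against vehicle 71 and 0, Liriopis seu Ophiopogonis Tuber high dose against vehicle 76 and 0, Liriopis seu Ophiopogonis Tuber medium dose against vehicle 64 and 1, Liriopis seu Ophiopogonis Tuber low dose against vehicle 83 and 2, Schisandrae Fructus high dose against vehicle 117 and 0, Schisandrae Fructus medium dose against vehicle 80 and 1, Schisandrae Fructus low dose against vehicle 27 and 1, Longan Arillus high dose against vehicle 13 and 0, Longan Arillus medium dose against vehicle 2 and 0, Longan Arillus low dose against vehicle 18 and 10, Zizyphi Semen high dose against vehicle 27 and 0, Zizyphi Semen medium dose against vehicle 5 and 0, Zizyphi Semen low dose against vehicle 6 and 1, Schisandrae Fructus high against low dose 32 and 0, Longan Arillus high against low dose 3 and 0, Zizyphi Semen high against low dose 9 and 0, Liriopis seu Ophiopogonis Tuber against Schisandrae Fructus at the high dose 16 and 0, Longan Arillus against Zizyphi Semen at the high dose 4 and 0. For Yijin-tang low dose against vehicle, 6 of 10 splits gave as many genes (2044 in the real and 5387 in the highest other), which points to a structure of the samples, the library labelled replicate 2. For Yijin-tang high against low dose, which holds the same library, the real split gave 3552 genes and each of the other 9 splits gave 1731 to 3278, which points to the same structure. For Liriopis seu Ophiopogonis Tuber high against low dose, 10 of 10 splits gave 0 genes by edgeR (320 at an unadjusted p under 0.05, 2 by DESeq2).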
